A study of Mus musculus with 4 samples.

How the data were processed

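RNA bound by eIF3c was profiled by eCLIP-seq, in which RNA crosslinked to a protein is recovered with an antibody and sequenced. The tissue was neural tube and somites of FVB mouse embryos at E11.5. Per the labels, lysate was spun to take out nuclei and mitochondria, treated with RNase I and divided: 5% was kept as input and the rest went to beads carrying an eIF3c antibody. RNA was then taken from the 105 kDa band of a membrane, the size of eIF3c, and from the same size range of the input lane. The 4 libraries are 2 eIF3c immunoprecipitates (IP) and 2 size-matched inputs, numbered 1 and 2 in each group. The labels do not say whether the replicates come from separate litters, so p-values measure the spread between these samples.

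The deposited values are raw counts of reads in windows of 10 nt, placed every 5 nt on each strand of mm10. The processing notes name cutadapt, STAR, UMI-tools and bedtools without versions or roles, and no normalization was applied to the deposited counts. The table holds 41494671 windows with at least 1 count in some library. Isolated runs of equal neighbouring windows showed that a read is counted in every window it overlaps, on average in 7.28 and 8.13 windows in IP replicates 1 and 2 and in 9.15 and 8.02 windows in inputs 1 and 2. Window totals divided by these means correspond to about 5359089 and 4125180 reads in the IP libraries and 3720371 and 12003457 in the inputs. How the authors assigned reads that map to more than 1 place is not stated. Because a read adds counts to neighbouring windows, window counts are not independent molecules, and the spread between replicates, not counting error, carries each test. Intervals and floors given for single sites cover counting error only. They do not allow for the choice of the site and its best window from these same counts, so such folds can be too large.

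Windows were joined to the GENCODE vM21 annotation of mm10. Every second window was kept, so that windows did not overlap, and summed on the sense strand over the exons of each transcript. The transcript of each gene with the largest sum over the 4 libraries represented the gene. Its windows were assigned to the 5′ UTR, the coding sequence (CDS, stop codon included) or the 3′ UTR. Between 0.948% and 1.43% of exonic counts were antisense. Windows within a gene but outside the exons of that transcript are called gene body outside the chosen exons. A contig beside the mm10 chromosomes was left out of gene counts and library sizes, but its windows were tested with the others. The deposited counts name it by a sequence identifier, and what it holds is not stated in the sources used here. CPM values, counts scaled to a common library size, use the gene totals and the TMM factors, and are not scaled by length.

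Genes and regions were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors from the gene counts, filterByExpr), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All tests were two-sided. The use of regions within a gene was tested with edgeR's diffSpliceDGE, which compares the fold change of 1 region with that of the other regions of the same gene. Windows with at least 10 counts in at least 2 libraries were tested with the same factors, and passing windows of the same direction that overlapped or touched were merged into sites. The share of mRNA counts per region was compared by an exact permutation test, whose smallest possible p with 2 libraries against 2 is 0.333. Differential counts were also computed with DESeq2 1.42.0. Other software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, numba 0.67.0 and matplotlib 3.10.9.

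Each input was taken from the same lysate as an IP according to the protocol, and the numbers in the labels pair them. Deviations of libraries of the same number from their group means had a correlation of -0.03 across genes, so the main tests carry no replicate term, and a fit with the replicate number as a block was run as an alternative. Genes are not independent replicates in that correlation.

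Gene lists were tested with camera (limma, preset correlation 0.01) on log2 CPM with a prior count of 2, and again with an estimated correlation. The same lists were tested with fry (limma). The 22 lists were the eIF3 complex, initiation factors, ribosomal proteins, other mRNAs with a 5′ terminal oligopyrimidine tract (TOP mRNAs), replication-dependent histones, nuclear noncoding RNAs, mitochondria-encoded mRNAs, Hox genes, the hedgehog, Wnt, BMP and TGF-beta, FGF, Notch and retinoic acid pathways, and markers of neural progenitors, neurons, somite derivatives, neural crest and dorsal root ganglia, erythroid cells, endothelium, macrophages, and liver, heart and limb. The lists, the tests, the settings of the alternatives and the rule for named genes were chosen before the data were examined. That rule takes the 12 largest rises and 8 largest falls among genes past the threshold, at or above the median abundance and changed the same way in both replicate pairs. It adds up to 4 members of each list with the smallest p, or the 2 most abundant members where none passed. It always includes Ptch1, Smo, Gli1, Gli2, Gli3, Eif3c, Jun and Btg1, and the 8 sites with the largest rise. A gene that this rule names is not reported here. Sequence composition was planned for a genome of the same build. The transcript sequences of GENCODE vM21 were used instead, so composition covers sites in exons only.

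Added after the data were seen were tests of list members per region (Fisher's exact test, Benjamini-Hochberg over all lists and regions), comparisons of list medians with 10000 random gene sets matched on count, profiles around the start codon, and gene tests without shared windows, with 1 window every 50 nt, with counts divided by windows per read, with CDS counts alone and without small RNA genes. Fisher's test and the random sets treat genes as independent, while members of a list can move together across the same 4 libraries. The correlation that camera estimated over whole transcripts was 0.456 for histones, 0.722 for ribosomal proteins, 0.324 for Hox genes and 0.246 for somite derivatives. The p-values of these 2 comparisons are therefore too small for such lists. The alternatives fixed in advance were DESeq2 size factors, library totals alone, no count filter, at least 50 counts in 2 libraries, the replicate block, the other set of non-overlapping windows, all windows, the transcript with the most windows, the DESeq2 Wald test and leaving out each library in turn. When 1 library was left out, edgeR estimated the spread from the group with 2 libraries, and the lone library was assumed to vary alike. Without an IP replicate that group was the inputs, which differed more from each other. A call lost there need not mean a smaller change.

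The tests were checked on simulated data in which 200 genes, regions or windows were changed. At a log2 change of 1, 15.0% of changed genes and 15.0% of changed regions were found. At a log2 change of 2 these shares were 91.0% and 96.0%. The test of region use found 3.0% and 37.0%, and 10 of its 50 calls were false, all but 1 of them in other regions of changed genes. A fall in the use of 1 region can therefore accompany a rise of another. For windows, 84.0% of rises and 40.0% of falls with a log2 change of 2 were found. In these simulations changes near 2-fold were mostly missed with 2 libraries per group. The gene and region simulations gave all libraries the same spread, while in the data the inputs differed from each other more than the IPs. Far more than 200 regions were also called in the data, so these shares need not hold there.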

Results

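RNA associated with eIF3c, a subunit of the translation initiation factor eIF3, was compared with size-matched input RNA in neural tube and somites of E11.5 mouse embryos. The data hold 2 eIF3c IP libraries and 2 input libraries. Over non-overlapping windows, the IP libraries held 19485087 and 16734434 counts and the inputs 17027331 and 48115683. Of these, 8568047 and 7397793 counts in the IPs and 7090798 and 19557087 in the inputs fell in genes. Protein-coding genes took 91.0% and 90.8% of gene counts in the IPs and 82.6% and 80.3% in the inputs, while small RNA genes took 5.37% and 5.67% against 12.3% and 14.0%. Among counts on the chromosomes that carry genes, exons took 61.9% and 64.4% in the IPs and 51.3% and 52.8% in the inputs. Log2 CPM of 16832 genes had a correlation of 0.95 between the IP replicates and 0.936 between the inputs. Set against sampling error, the inputs differed more. For counts divided by windows per read, the chi-square per degree of freedom was 3.78 between the IPs and 18.5 between the inputs.

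The first question was where on mRNAs the eIF3c signal lay. The enrichment over input lay in 5′ UTRs, the stretch that initiating ribosomes scan. Counts in 5′ UTRs made up 26.4% ± 4.01 (SD, n = 2) of mRNA counts in the IP libraries and 6.39% ± 0.337 (SD, n = 2) in the inputs. The CDS held 37.7% ± 1.04 in the IPs and 49.2% ± 6.06 in the inputs (SD, n = 2 each), and the 3′ UTR 35.9% ± 5.04 and 44.4% ± 6.40. The difference was 20.0 percentage points for 5′ UTRs, -11.5 for the CDS and -8.53 for 3′ UTRs. The 5′ UTR and CDS shares of the IPs did not overlap those of the inputs, nor did the 3′ UTR shares. The exact two-sided permutation p was 0.333 for each region, the smallest that 2 against 2 libraries can give.

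**Figure D1:**
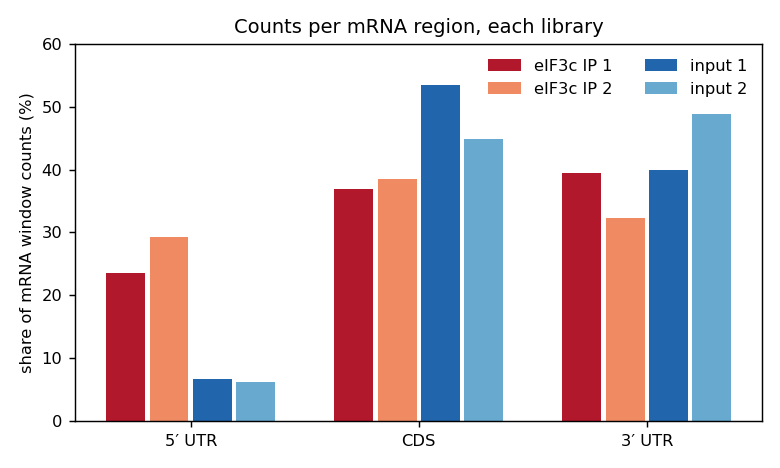
Share of mRNA window counts (percent, y axis) in the 5′ UTR, CDS and 3′ UTR (x axis), with 1 bar per library. The 5′ UTR bars stand at 23.6% and 29.2% in the IPs and at 6.62% and 6.15% in the inputs.

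Read density was also higher in 5′ UTRs within genes. In 2624 genes with at least 200 CDS counts in every library, the median density of the 5′ UTR over that of the CDS was 3.33 and 3.77 in the IPs and 0.618 and 0.781 in the inputs. Aligned at the start codon of 2251 genes, the 100 nt before the codon held 4.79 and 5.48 times the mean count of the CDS in the IPs, against 0.893 and 1.14 times in the inputs. The IP signal reached past the start codon: the first 100 nt of the CDS held 2.52 and 2.73 times the CDS mean, and the stretch from 100 to 200 nt held 1.54 and 1.57 times. From 300 to 400 nt it was back at 1.09 and 1.02 times, beside 1.049 and 1.028 times in the inputs. These profiles were added after the data were seen and carry no test.

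**Figure D2:**
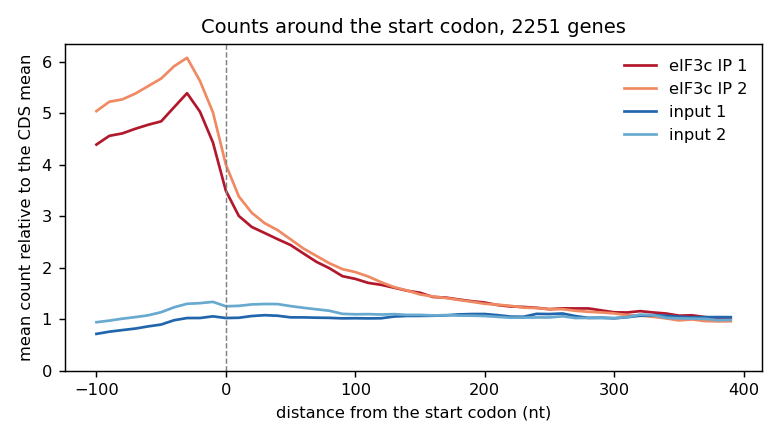
Mean count per 10 nt relative to the CDS mean (y axis) against the distance from the start codon in nt (x axis) for 2251 genes, 1 line per library. Both IP lines lie far above the input lines before the codon and meet them about 300 nt into the CDS.

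By gene, rises were most frequent in 5′ UTRs. Of 8893 tested 5′ UTRs, 4981 were higher in the IP and 24 lower (edgeR, adjusted p), with a median log2 fold change of 2.18. In the CDS 198 of 12656 genes were higher and 261 lower, with a median of -0.25. Regions were scaled by gene totals that include 5′ UTR counts, so part of the CDS shift can follow from the 5′ UTR rise. Scaled by CDS totals and factors alone, 208 of 12610 CDS were higher and 45 lower, with a median of -0.007. In the 3′ UTR 21 of 11237 were higher and 99 lower, with a median of -0.20. The 5′ UTR log2 fold change lay above that of the CDS in 8456 of 8652 genes with both regions tested. Among 5′ UTRs that rose were those of Hes1, a Notch target that represses neuronal differentiation, with a log2 fold change of 4.30 ± 0.43 (SE, n = 2 and 2, adjusted p = 3.5e-05), Dusp6, a feedback inhibitor of FGF signalling, with 4.03 ± 0.33 (adjusted p = 2.5e-05), and Crabp2, a retinoic acid carrier, with 3.89 ± 0.36 (adjusted p = 3.0e-05). Without input replicate 1 the Hes1 5′ UTR was at 5.04. In none of these 3 genes did the CDS or the 3′ UTR pass. The number of 5′ UTRs that rose was 2853 without IP replicate 2. Counts for the other regions moved further: CDS rises came to 74 without IP replicate 1, 72 without IP replicate 2 and 309 without input replicate 1, and CDS falls to 50, 47 and, without input replicate 2, 950. Lower 5′ UTRs came to 13 without either IP replicate and 45 without input replicate 2. Higher 3′ UTRs came to 4, 5 and 122 without IP replicate 1, IP replicate 2 and input replicate 2, and lower 3′ UTRs to 31, 18 and 232 in that order and to 189 without input replicate 1.

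**Figure D3:**
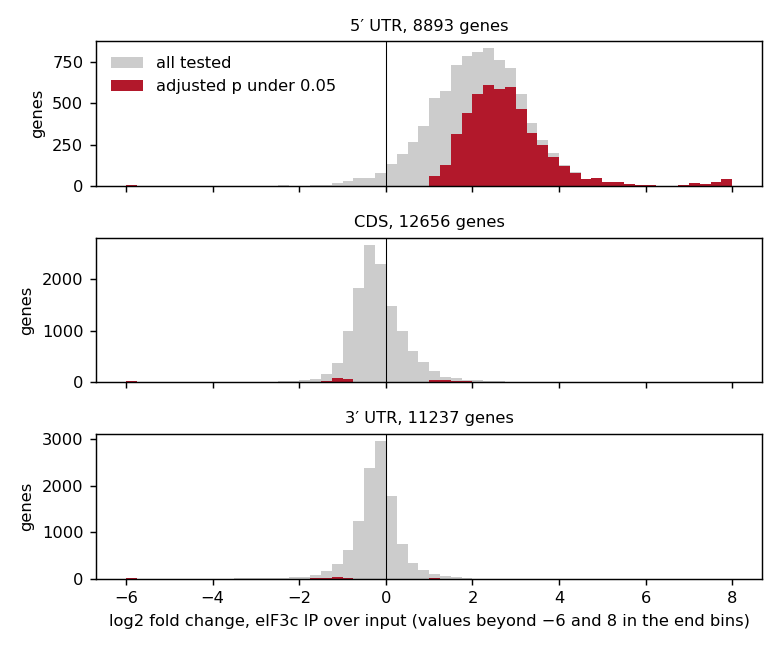
Numbers of genes (y axis) by log2 fold change of IP over input (x axis) in the 5′ UTR, CDS and 3′ UTR, all tested genes in grey and those past the adjusted threshold in red. The 5′ UTR distribution centres on 2.18, those of the CDS and 3′ UTR on -0.25 and -0.20.

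Within genes, use of the 5′ UTR relative to the other regions was higher in the IP in 5138 of 8746 genes and lower in 4 (edgeR diffSpliceDGE). CDS use was lower in 422 of 11522 genes and higher in 15, and 3′ UTR use lower in 463 of 10930 and higher in 5. The few genes with lower 5′ UTR use or higher 3′ UTR use are named here after their values were seen, and the 15 with higher CDS use are not named: 5′ UTR use fell in Mettl26, Rabggtb, Rsbn1 and Sptb, and 3′ UTR use rose in AC129217.1, Atad3a, Irak1, Llgl1 and Tal1. The 3′ UTR itself passed as higher only in AC129217.1, with a log2 fold change of 1.66. In Atad3a (0.73), Irak1 (-0.30), Llgl1 (0.10) and Tal1 (0.03) it did not pass. The Sptb 5′ UTR, for example, held 17.9 ± 5.11 CPM in the inputs and 1.59 ± 0.159 in the IPs (SD, n = 2). The Rsbn1 5′ UTR had 0 IP counts against 72 input counts and was at least 15.1-fold lower, with a floor of 3 counts over the group. With the replicate block, 5′ UTR use was lower in 8 genes and 3′ UTR use higher in 10. Without IP replicate 2, 5′ UTR use was higher in 1898 genes and lower in 1, CDS use lower in 21 and 3′ UTR use lower in 28, and 0 CDS and 0 3′ UTRs were used more (edgeR, with 472 and 418 regions at an unadjusted p under 0.05). Without IP replicate 1, CDS use was lower in 74 genes and higher in 2, 3′ UTR use lower in 134 and higher in 3, and 5′ UTR use higher in 3112. Without input replicate 2, 5′ UTR use was lower in 16 genes, CDS use higher in 54 and lower in 708, and 3′ UTR use higher in 86. CDS use was higher in 39 genes without input replicate 1.

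Summed over whole transcripts, the question was which RNAs were enriched with eIF3c. Of 16832 genes tested, 806 were higher in the IP and 477 lower (edgeR, 3768 at an unadjusted p under 0.05). The genes that rose were mostly protein-coding, and those that fell were mostly small RNAs: 720 of 13640 protein-coding genes rose and 60 fell, while 0 of 292 snoRNA genes rose and 191 fell, with a median log2 fold change of -2.37. Among 345 snRNA genes 98 fell and 1 rose. Without small RNA genes, 859 genes were higher and 230 lower. With CDS counts alone, 208 were higher and 45 lower, and of 754 calls tested there 156 kept their call and direction. A rise over the whole transcript can therefore come from the 5′ UTR alone. Higher and lower genes came to 214 and 115 without IP replicate 1, 127 and 150 without IP replicate 2, 1300 and 790 without input replicate 1, and 1431 and 1116 without input replicate 2. Of the 1283 calls, 325 recurred in the same direction without IP replicate 1 and 274 without IP replicate 2.

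Of the 12 largest rises 6 were histone genes. Hist1h2bn (ENSMUSG00000095217.1, mm10 13:21754123-21754503) stood at 892 ± 214 CPM in the IP and 65.4 ± 12.3 in the input (SD, n = 2), a log2 fold change of 3.77 ± 0.26 (SE, adjusted p = 0.00105). Hist1h2bg, Hist1h2ae, Hist1h1d, Hist1h2bb and Hist1h2bk rose by log2 fold changes of 3.63, 3.52, 3.22, 3.05 and 3.01. The other 6 of the 12 were Gm42778 (4.09), Usmg5 (3.70), a subunit of mitochondrial ATP synthase, Cks2 (3.45), a cell cycle regulator, Mir5100 (3.28), Erh (3.09) and the mitochondrial tRNA gene mt-Ta (3.03). In Usmg5, Cks2 and Erh most of the signal was in the 5′ UTR: the Cks2 5′ UTR held 77.4 ± 16.6 CPM in the IP and 7.16 ± 2.15 in the input (SD, n = 2), and its CDS 9.21 ± 2.13 and 0.803 ± 0.727. Mir5100 lost its call without IP replicate 1, where its log2 fold change was 2.44, and came to 4.07 without input replicate 2. The other 11 kept their calls without each library, though without input replicate 1 mt-Ta came to 3.78, Hist1h2bg to 4.21 and Hist1h2bk to 3.67. The Cks2 CDS had no call without IP replicate 2 (log2 fold change 3.12, adjusted p = 0.0643) and was at 4.91 without input replicate 2.

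The 8 largest falls were Gm43338 (-5.88 ± 1.08, SE, n = 2 and 2), the snRNA genes Gm23144 (-5.73), Gm25312 (-4.95), Gm25698 (-4.91), Gm24830 (-4.76) and Gm24207 (-4.75), the C/D box snoRNA Snord37 (-5.03) and Rell2 (-4.86). They were scarce in the IPs and uneven in the inputs: Snord37 stood at 26.3 ± 0.871 CPM in the IP and 863 ± 761 in the input (SD, n = 2), with an adjusted p of 0.00541. Of the 8, 7 (all but Gm25312) lost their call without either IP replicate. Without an input replicate these calls stayed, but sizes moved: Rell2 was at -1.97, Gm43338 at -3.77, Gm23144 at -3.77, Snord37 at -3.64, Gm25312 at -3.86, Gm25698 at -3.24 and Gm24207 at -2.56 without input replicate 1, and Gm24830 at -2.51 without input replicate 2. Without input replicate 2 the other 7 lay between -5.58 and -6.70, and without input replicate 1 Gm24830 was at -5.61. Gm43338 was at -7.59 and -5.16 without IP replicates 1 and 2, and Gm24207 at -4.15 and -5.71.

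Of the 22 gene lists, 6 differed from the other genes (camera, preset correlation), and 0 did with an estimated correlation (1 list at an unadjusted p under 0.05). That loss need not come from correlation within the lists. With an estimated correlation camera uses the few residual degrees of freedom of 4 libraries. Nuclear noncoding RNAs had an estimated correlation of -0.0235, below the preset 0.01, yet their unadjusted camera p went from 3.5e-07 to 0.033. With fry, which asks whether a list moved without comparing it with other genes, 1 passed, the neural progenitors (adjusted p = 0.0471). From CDS counts alone 3 lists passed by camera, histones (1.1e-33), Hox genes (9.1e-07) and other TOP mRNAs (0.00576), and 0 with an estimated correlation (0 at an unadjusted p under 0.05, adjusted p = 0.786 for each of the 3). Replication-dependent histones, whose mRNAs end in a stem-loop rather than a poly(A) tail, rose most. Of 63 tested histone genes 38 were higher over all genes tested, 50 adjusted over the list alone, and 0 lower, with a median log2 fold change of 1.59 (adjusted p = 6.5e-21, and adjusted p = 0.657 with an estimated correlation). Higher histone regions were more frequent than in other genes: 36 of 43 5′ UTRs, 39 of 59 CDS and 9 of 43 3′ UTRs were higher, against 55.9%, 1.26% and 0.107% of other genes (Fisher's exact test, adjusted p = 0.00153, 9.1e-56 and 5.8e-16). This test counts genes as independent, which histone genes measured in the same 4 libraries are not. Hist1h1d, an H1 linker histone, held 1272 ± 64.3 CPM in its 5′ UTR in the IP and 40.2 ± 25.1 in the input (SD, n = 2). Many histone CDS are near-identical in sequence, and Hist1h1b and Hist4h4, which share under 10% of their 25 nt stretches with other histone genes, rose by log2 fold changes of 2.97 and 2.62. Without input replicate 1 the Hist1h1d 5′ UTR log2 fold change went from 5.00 to 5.82, and the histone 5′ UTR median from 3.31 to 4.93. Higher histone CDS numbered 23 without IP replicate 1 and 28 without IP replicate 2.

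Nuclear noncoding RNAs were lower as a list. Of 12 tested 6 were lower, 9 adjusted over the list alone, with a median of -0.87 (camera adjusted p = 3.9e-06, and adjusted p = 0.657 with an estimated correlation). They included Rn7sk, the 7SK RNA that holds back transcription elongation, at -2.94 ± 0.35 (SE, n = 2 and 2), the ribozyme RNA Rmrp at -2.34, and Rian at -1.72. Rian shares 27.8% of its windows with another gene and was at -1.12 without them. Rmrp is annotated as 2 overlapping genes on the same reads, which share 100% and 89.4% of their windows, so the same RNA is counted 2 times among the 12 and the 6, and both lost their call without IP replicate 1. Of 7 mitochondria-encoded mRNAs 0 passed by edgeR (2 at an unadjusted p under 0.05) or by DESeq2, and 0 adjusted over the list alone, with a median of -0.58 (camera adjusted p = 0.471, and 0.00875 without input replicate 2). The most abundant, mt-Cytb and mt-Co1 of the respiratory chain, were at -0.71 and -0.37 and passed without input replicate 2, at -1.16 and -0.91.

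In signalling pathways some members rose, and the shares of pathways were not compared with each other. Over all protein-coding genes 720 of 13640 rose. The single genes that rose in the FGF, Wnt and retinoic acid lists are near or below that share and are no result about those pathways. The BMP and TGF-beta list had 8 of 32 members higher, also 8 adjusted over the list alone, with a median of 0.25 (camera adjusted p = 0.00984, and adjusted p = 0.657 with an estimated correlation). It was led by Id1, a BMP target that blocks bHLH factors, at 1.59 ± 0.18 (SE, n = 2 and 2), Smad6, an inhibitor of the pathway, at 1.76 ± 0.25, and the ligands Tgfb2 (1.17) and Bmp5 (1.14). With CDS counts alone the list had an adjusted p of 0.610. Dusp6 was the 1 of 27 FGF genes that rose, at 1.47, and the same 1 adjusted over the list alone (camera adjusted p = 0.143, and 0.0382 without input replicate 2). Of 26 Notch genes Hes1 (1.61) and Dll1 (1.11) rose, also 2 adjusted over the list alone (0.557). Crabp2, at 1.85, was the 1 of 18 retinoic acid genes, and Tcf7l2, a transcription factor of Wnt signalling, at 1.20, the 1 of 44 Wnt genes, in each also 1 adjusted over the list alone (0.507 and 0.471). The retinoic acid list had a median of -0.01 and a mean of 0.17. Smad6, Tgfb2, Bmp5, Dll1 and Tcf7l2 lost their calls without either IP replicate, and Dusp6, Hes1 and Crabp2 without IP replicate 2. Of these genes only Id1 kept its call with CDS counts alone (1.25). The others did not pass there: Dll1 (-0.25), Tcf7l2 (-0.09), Hes1 (0.03), Dusp6 (0.08), Smad6 (0.08), Tgfb2 (0.08), Crabp2 (0.60) and Bmp5 (0.73).

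The hedgehog pathway, which patterns the ventral neural tube and the somites, had 0 of 26 members past the threshold in whole transcripts (edgeR, 5 at an unadjusted p under 0.05, 2 higher by DESeq2), also 0 adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.785). Its signal was in 5′ UTRs, as elsewhere: 12 of 22 hedgehog 5′ UTRs were higher, 54.5% beside 56.0% of other genes, with a median log2 fold change of 1.90 (Fisher's exact test, adjusted p = 1.00). Gli1, a transcription factor and target of the pathway, rose in its 5′ UTR by 2.68 ± 0.37 (SE, n = 2 and 2, adjusted p = 0.000211), from 5.18 ± 2.00 CPM to 34.2 ± 2.93 (SD, n = 2). The Gli2 5′ UTR rose by 2.17 ± 0.41 (adjusted p = 0.00212), that of Gli3, a repressor in the absence of ligand, by 1.94 ± 0.48 (0.0120) and that of Smo, the signal transducer, by 1.37 ± 0.38 (0.0225). The Ptch1 5′ UTR, of the receptor, had a log2 fold change of 0.92 ± 0.51 (0.285). Over whole transcripts the log2 fold changes were 0.69 for Gli1, -0.48 for Gli2, -0.09 for Gli3, -0.19 for Ptch1 and -0.03 for Smo, with adjusted p between 0.113 and 0.954. The Smo 3′ UTR fell by 1.21 ± 0.33 (0.0214). Without input replicate 2, Gli1 (0.92) and Gli2 (-0.67) passed over whole transcripts. The most abundant hedgehog genes were Gsk3b (0.41) and Csnk1a1 (0.52). The Gli3 5′ UTR did not pass without IP replicate 2 (adjusted p = 0.255), and 8 hedgehog 5′ UTRs were higher there. Nor did that of Smo pass without IP replicate 1 (0.0981), IP replicate 2 (0.188) or input replicate 1 (0.0655), and without input replicate 2 it came to 2.11.

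Jun, Btg1 and Eif3c, named in advance, all rose in their 5′ UTR. Jun, an AP-1 transcription factor (ENSMUSG00000052684.4, mm10 4:95049034-95052222), stood at 1392 ± 383 CPM in the IP and 344 ± 58.9 in the input (SD, n = 2), a log2 fold change of 2.02 ± 0.26 (SE, adjusted p = 0.00524). Its 5′ UTR rose by 3.55 ± 0.33 (adjusted p = 3.0e-05), while its CDS was at -0.29 ± 0.30 (0.608) and its 3′ UTR at -0.24 ± 0.27 (0.646). Btg1, an antiproliferative gene, rose by 1.31 ± 0.20 over the transcript (0.00971) and by 2.94 ± 0.31 in its 5′ UTR (4.7e-05), but lost the transcript call without IP replicate 2. Eif3c itself did not pass over the transcript, at -0.27 ± 0.22 (0.543), and rose in its 5′ UTR by 3.04 ± 0.36 (8.4e-05). The 5′ UTR calls of Jun, Btg1 and Eif3c stood without each library in turn.

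**Figure D4:**
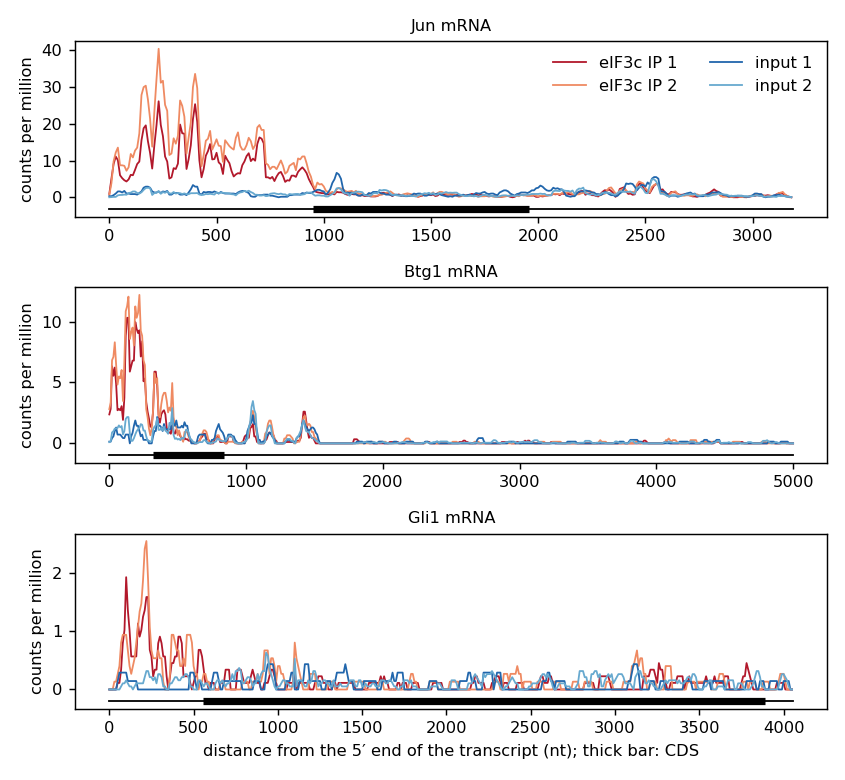
CPM per window (y axis) along the Jun, Btg1 and Gli1 mRNAs (distance from the 5′ end in nt, x axis), 1 line per library, with the CDS as a thick bar. IP lines rise above input lines in the 5′ UTR, whose log2 fold changes are 3.55 in Jun, 2.94 in Btg1 and 2.68 in Gli1.

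Markers of the dissected tissue rose in part. Somite derivatives had 7 of 29 genes higher, 14 adjusted over the list alone, with a median of 0.64 (camera adjusted p = 0.0108, and adjusted p = 0.891 with an estimated correlation). En1 (1.76 ± 0.23, SE, n = 2 and 2), Prrx1 (1.48), Foxc2 (1.31) and Meox2 (1.15), transcription factors of the dermomyotome, limb mesenchyme and sclerotome, were among them. In their 5′ UTRs 23 of 25 somite genes were higher, 92.0% beside 55.9% of other genes (Fisher's exact test, adjusted p = 0.00153). Random sets matched on count had a median 5′ UTR log2 fold change of 2.34, and 1.2% of them were as high as the somite list. Neural progenitor genes had 3 of 27 higher, among them Fabp7 (1.76), a fatty acid carrier of radial glia, and Irx3 (1.38), a homeobox factor, with 6 higher and 1 lower adjusted over the list alone and a median of 0.33 (camera adjusted p = 0.0132, and adjusted p = 0.657 with an estimated correlation). The median 5′ UTR log2 fold change of somite genes was 2.90 beside 2.18 for all genes, and 17 of 26 were higher without IP replicate 2. With CDS counts alone the camera adjusted p was 0.216 for somite and 0.610 for neural progenitor genes. Of 30 neuron markers 6 rose, 7 and 1 lower adjusted over the list alone, among them Nhlh2 (1.049), Lhx1 (1.03), Stmn3 (0.91) and Syt1 (0.85, with no call under the replicate block and -0.24 from CDS counts alone), with a camera adjusted p of 0.0746. Foxc2, Meox2, Irx3 and the 4 neuron genes lost their calls without either IP replicate, and Prrx1 and Fabp7 without IP replicate 2. Of 16 neural crest and dorsal root ganglion genes Tfap2a rose (0.94, lost without either IP replicate), with 3 adjusted over the list alone (0.220), and all 9 tested 5′ UTRs of the list were higher (Fisher's exact test, adjusted p = 0.0490), but 6 of 10 were without IP replicate 2. Their median of 2.62 was reached by 19.8% of random sets matched on count, which had a median of 2.30. With no count filter 9 of 15 5′ UTRs of this list were higher, beside 5657 of 13973 over all genes, so the filter had left out members that did not pass. Of the genes named in this paragraph, Prrx1, Fabp7, Stmn3 and Tfap2a kept a call with CDS counts alone. En1, Foxc2, Meox2, Irx3, Nhlh2, Lhx1 and Syt1 did not.

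Hox genes, which set segment identity along the body axis, had Hoxb8 (1.27), Hoxb7 (1.27) and Hoxb6 (1.02) higher among 39, the same number adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.0746). These 3 lost their calls without either IP replicate, and the list passed without IP replicate 2 (0.00303) and without input replicate 2 (0.0328). In the CDS 6 of 39 Hox genes were higher, 15.4% beside 1.52% of other genes (Fisher's exact test, adjusted p = 0.000411). In 5′ UTRs 12 of 30 were higher, 40.0% beside 56.1% of other genes (Fisher's exact test, adjusted p = 0.423). The Hox 5′ UTR median was 1.61, beside 2.25 for random sets matched on count. From CDS counts alone the list had a median of 0.69 (camera adjusted p = 9.1e-07, and adjusted p = 0.786 with an estimated correlation). The Hoxb7 CDS, for example, rose by 1.46 ± 0.32 (SE, n = 2 and 2, adjusted p = 0.00544). Without IP replicate 1 the Hoxb7 CDS did not pass (0.0573) and 1 Hox CDS was higher, and without IP replicate 2 there were 4.

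**Figure D5:**
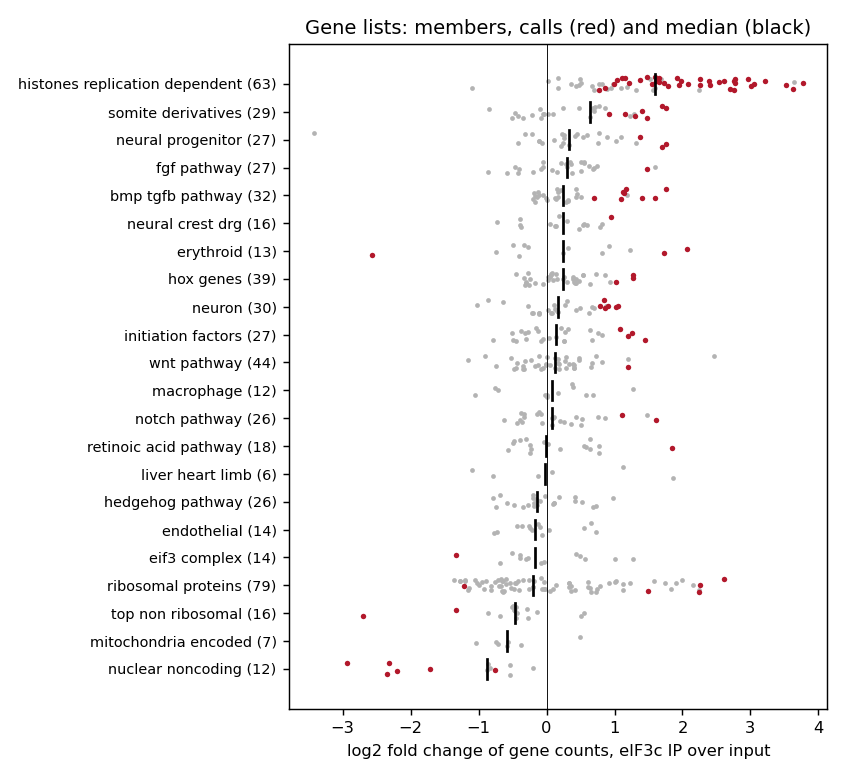
Log2 fold change of IP over input (x axis) of each tested member of the 22 gene lists (y axis, number of members in brackets), in red where past the adjusted threshold, with the list median as a black bar. Histone genes have a median of 1.59 and nuclear noncoding RNAs of -0.87.

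Genes of the translation machinery gave few calls over whole transcripts, in both directions. Ribosomal protein genes had 4 of 79 higher, among them Rps27a (2.61), Rpl27 (2.26) and Rpl28 (2.24), and Rplp0 (-1.22) lower, with the same counts adjusted over the list alone. Their median was -0.19, their mean 0.07 and the camera direction upward (adjusted p = 0.876), and the list passed upward without input replicate 1 (0.00549) and downward without input replicate 2 (0.00875). In 5′ UTRs 18 of 70 ribosomal protein genes were higher, 25.7% beside 56.3% of other genes (Fisher's exact test, adjusted p = 6.3e-06), with a median of 1.12 beside 2.18 for all genes. That difference was absent without input replicate 1, where the median was 2.42 beside 2.24 for all genes. It was larger without input replicate 2, at 0.531 beside 2.275. With 2 inputs, nothing shows which of them is the odd library. With the replicate block 31 of 70 were higher, with a median of 1.36. Higher 5′ UTRs numbered 12 without IP replicate 1, 5 without IP replicate 2 and 16 without input replicate 2. Other TOP mRNAs had 2 of 16 lower, 3 adjusted over the list alone, with a median of -0.46 (camera adjusted p = 0.0118, and adjusted p = 0.891 with an estimated correlation). The call was lost without IP replicate 1 (0.296) and without input replicate 1 (0.117). The 2 were the snoRNA host gene Gas5 (-2.70), which shares 78.3% of its windows with another gene and was at -1.25 without them, and Eif3h (-1.33), also the 1 of 14 eIF3 subunits that fell, 2 adjusted over the list alone (camera adjusted p = 0.714). Eif3h lost its call without either IP replicate and under the replicate block. Of 27 initiation factors Eif6 (1.44), Eif2s3x (1.26), Eif1b (1.20) and Eif5a (1.07) rose, 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.471). Without IP replicate 2 all 4 lost their calls, and without IP replicate 1 all but Eif6 did. Rpl27 lost its call without IP replicate 2, and Rplp0 without either IP replicate.

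Markers of cell types that a dissection can carry along gave few calls. Among 13 erythroid genes the globins Hbb-bh1 (2.07) and Hbb-bs (1.73) rose and Tal1 (-2.57) fell, the same numbers adjusted over the list alone (camera adjusted p = 0.471). All 3 lost their calls without IP replicate 2, and Tal1 also without IP replicate 1 and by DESeq2, with log2 fold changes of -1.12 without input replicate 1, -3.31 without input replicate 2 and 0.07 with 1 window every 50 nt. By edgeR 0 of 14 endothelial, 0 of 12 macrophage and 0 of 6 liver, heart and limb genes passed (0, 0 and 1 at an unadjusted p under 0.05, and 0, 0 and 1 by DESeq2), with 0, 0 and 1 (higher) adjusted over the list alone (camera adjusted p = 0.687, 0.640 and 0.861). Their most abundant members were Cdh5 (-0.35) and Kdr (-0.09), Mrc1 (-0.76) and Cx3cr1 (0.37), and Actn2 (0.08) and Hand2 (1.85). The liver, heart and limb list had a median of -0.02 and a mean of 0.17. Without input replicate 2, Mrc1 (-1.32) and Hand2 (2.42) passed.

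At the level of single windows, 314842 were tested and 73812 were higher and 21855 lower, which merged into 8758 sites higher and 4049 sites lower in the IP (edgeR, 122140 windows at an unadjusted p under 0.05). These totals included 1842 windows, 23 higher sites and 47 lower sites on the contig beside the mm10 chromosomes. Sites in 5′ UTRs made up 62.6% of the higher sites, 5484 in 3013 genes with a median length of 40 nt, although 5′ UTR windows were 22.0% of those tested. In 5′ UTRs 77.0% of tested windows were higher, beside 7.005% in the CDS and 0.564% in 3′ UTRs. In small RNAs 51.5% of windows were lower. Of 865 higher sites in gene bodies outside the chosen exons, 415 (48.0%) lay in the 5′ UTR of another annotated transcript, beside 4 of 651 (0.614%) lower sites. Without IP replicate 1 there were 2485 higher and 1699 lower sites. Without IP replicate 2 there were 0 of either (edgeR, 39371 windows at an unadjusted p under 0.05). Lower sites came to 2591 without input replicate 1 and 1681 without input replicate 2.

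The 8 higher sites with the largest fitted rise all had 0 input counts in their best window, so their folds are lower bounds against a floor of 3 counts over the group. In Rcc2, a regulator of mitosis, a 175 nt site in the 5′ UTR (mm10 4:140701481-140701655) was at least 85.3-fold higher, with 80 and 81 IP counts in its best window. In Fosb, another AP-1 gene, a 65 nt site in the 5′ UTR (7:19309931-19309995) was at least 54.0-fold higher. A 35 nt site in the gene body of Stx8 outside exons (11:68094196-68094230) was at least 188-fold higher, with 268 and 87 IP counts. The other 5 lay outside genes, at 3:107250661-107250695, 11:46315876-46315910, 2:164806056-164806090, 11:120231071-120231100 and 10:76904636-76904670, and were between at least 47.7-fold and at least 83.7-fold higher. Each of the 8 had an adjusted p of 0.00116 (edgeR), and as with all sites the calls were absent without IP replicate 2.

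In the genes named in advance, the site with the smallest p was in the 5′ UTR in Btg1 (10:96616996-96617295, 37.8-fold higher in its best window), Jun (4:95051266-95052210, 35.6-fold), Gli1 (10:127341726-127341770, 10.2-fold), Eif3c (7:126566146-126566225, 9.53-fold) and Smo (6:29735691-29735740, 3.83-fold), with adjusted p between 0.00116 and 0.0156. In Gli3 it was at 13:15463771-15463815, in an exon of another, noncoding transcript, with 61 IP counts against 1 input count, a ratio of 96.9 with a counting interval of 16.8 to 3889 (95%, Clopper-Pearson). In Gli2 it was a lower site in the CDS (1:118837386-118837415), with 1 IP count against 306 input counts, a ratio of 0.00519 (0.000131 to 0.0291). In Ptch1 it was a lower site in the gene body outside exons (13:63568241-63568275), with 13 and 1 IP counts against 3324 and 1398 input counts. Counts and ratios in this paragraph are those of the best window of each site, picked by p. They can overstate the change of the whole site, and the intervals leave this choice out. The strongest higher site of Ptch1, looked up after the data were seen, was at 13:63566156-63566225, also outside exons and 9.08-fold higher (adjusted p = 0.00216). These calls were also absent without IP replicate 2.

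The sequence of higher sites was compared with tested windows of the same region that did not pass. Sites in 5′ UTRs held 53.7% ± 12.6 pyrimidines (SD, 5484 sites) against 51.9% ± 19.7 (15756 windows), and 59.9% G plus C against 66.2%. The pyrimidine difference of 1.81 points was 2.54 against windows of the same genes and 5.43 with the single window of smallest p for each site. Sites in 3′ UTRs were richer in pyrimidines, at 60.7% ± 21.2 (202 sites) against 54.6% ± 19.1, and poorer in G plus C, at 32.6% against 41.9%. In the CDS 840 sites held 52.7% pyrimidines against 48.8% and 55.4% G plus C against 52.9%. The permutation p over 100000 resamples was between 1e-05, the smallest they can give, and 3e-05, with adjusted p between 1.5e-05 and 3e-05 over 6 comparisons. Sites are not independent replicates, and each difference was smaller than the spread between sites.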

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

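The tests of the 3 patterns in this part, those with matched windows, matched random sets and dissimilar histone genes, were chosen after the data were seen, and the one without input replicate 1 after its own result was seen.

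A contig beside the mm10 chromosomes took a mean of 30.85% ± 1.596 of window counts in the IPs and 23.67% ± 3.626 in the inputs (SD, n = 2). It was left out of the gene and region comparisons, while its windows were in the window tests and site totals above. The share is given here because it is a signal above the input in data outside the gene and region comparisons. Its site with the most IP counts, at 14906-14950, was 4.235-fold higher in the IP, with 111028 and 75667 IP counts against 16362 and 53698 input counts (edgeR adjusted p = 0.00489), and is given for the same reason. On the contig 23 sites were higher and 47 lower. Of its 1842 tested windows 88 were higher and 405 lower, with a median log2 fold change of -0.81. As with all sites, these calls were absent without IP replicate 2. What the contig holds is not stated in the sources used here, and no explanation was tested.

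The rise of 5′ UTRs in the IP was set against GC content and depth, and no biological explanation was tested, since the design names none. Windows of 5′ UTRs had a median log2 fold change of 2.733 (69268 windows). CDS windows more than 300 nt after the start codon, drawn to the same G plus C content, had a median of -0.5891, and CDS windows drawn to the same depth one of -0.7192. Both argue against these 2 as the whole cause. Depth here is the total count, IP counts included, and windows could reach the minimum count through the IPs alone. Selection of windows by count was therefore not taken out. Other technical causes, such as the yield of crosslinking, stay open.

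The rise of histone CDS was set against a short CDS, GC content and reads shared between near-identical copies, and no biological explanation was tested. The list had a median CDS log2 fold change of 1.577 (59 genes), above 0.26 for random sets matched on CDS length and count and -0.175 for sets matched on G plus C and count. In both tests 0 of 10000 sets were as high, a permutation p of 0.0001, the smallest they can give. As the sets lack the correlation within the list, this p does not measure the spread between libraries. The 4 genes with under 10% of 25 nt stretches in another histone gene (Hist1h1t, Hist1h1a, Hist4h4 and Hist1h1b) had a median of 2.117, which argues against shared reads as the whole cause. The missing poly(A) tail of these mRNAs was not tested as a technical cause and stays open.

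The smaller rise of ribosomal protein 5′ UTRs was set against short 5′ UTRs, mRNA abundance and a single input library, and no biological explanation was tested. Random sets matched on 5′ UTR length and count had a median of 2.45 and sets matched on CDS count in the inputs one of 2.22, beside 1.125 for the list, and with the shortest annotated 5′ UTRs the gap was smaller, 1.646 beside 2.456. In each 0 of 10000 sets were as low, a permutation p of 0.0001, the smallest they can give. With all 4 libraries, genes of like length or count thus did not share the smaller rise. The sets hold genes drawn singly, without the correlation within the list, so this p does not measure the spread between libraries. Without input replicate 1 the list median lay 0.185 above that of all genes, while with all libraries it lay 1.054 below and without each other library between 0.824 and 1.74 below. The pattern therefore depends on which input is used. This comparison was chosen after its own result was seen and cannot tell which of the 2 inputs is the odd library.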

How the results depend on the processing

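The tests with CDS counts alone, without small RNA genes, without shared windows, with 1 window every 50 nt, with counts divided by windows per read, and of the lists with an estimated correlation together with the replicate block or with CDS counts alone were chosen only after the results were seen. Where a result changed, the cause was not tested, except that fewer libraries, or fewer or more genes and windows tested, follow from the setting itself. Without an IP replicate the spread was also taken from the 2 inputs, which differed more from each other than the IPs. A call could then be lost at a similar size: Bmp5 was at 1.13 without either IP replicate, beside 1.14. In other genes the size moved too, as in Dll1, at 0.84 without IP replicate 2 beside 1.11.

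Of 81 named genes, those with the same direction and side of the threshold numbered 80 with DESeq2 size factors, 80 with library totals, 79 with no filter, 81 with at least 50 counts, 79 with the replicate block, 79 with the other set of windows, 73 with all windows, 78 with the transcript with the most windows and 78 with the DESeq2 Wald test. They numbered 79 of 80 without shared windows, 79 with 1 window every 50 nt, 80 with counts divided by windows per read, 71 of 71 without small RNA genes and 32 of 64 with CDS counts alone. Without IP replicate 1 they numbered 48, without IP replicate 2 41, without input replicate 1 78 and without input replicate 2 72. Of genes past the threshold, reversed were Tcf7l2 (-0.088), Dll1 (-0.25), Syt1 (-0.24) and Jun (-0.047) with CDS counts alone and Tal1 (0.073) with 1 window every 50 nt. Genes not past the threshold whose sign changed were Smo with library totals, 1 window every 50 nt and CDS counts alone, and Gsk3b, Csnk1a1, Actn2, Gli3 and Ptch1 with CDS counts alone. Without IP replicate 1 it changed in Smo, without IP replicate 2 in Kdr, without input replicate 1 in mt-Co1, Mrc1 and Eif3c, and without input replicate 2 in Kdr, Actn2 and Smo. Of the 22 lists, 22 kept their side of the threshold with library totals, with the block and without small RNA genes, and 16 with an estimated correlation, where 6 lost their call. The ribosomal protein list reversed without input replicate 2, with an adjusted p from 0.00549 to 0.348 over the 4 left-out libraries (0.00875 there).

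With no filter 1308 genes were higher and 1007 lower, 474 CDS lower, and 33 3′ UTRs higher and 160 lower. Of 13973 5′ UTRs tested with no filter, 5657 were higher and 34 lower, a smaller share than the 4981 of 8893 with it. With CDS counts alone 208 genes were higher and 45 lower, and 3 lists passed. The DESeq2 Wald test gave 724 lower genes, and without small RNA genes 230 were lower. 5′ UTR use was lower in 2 genes with at least 50 counts and 8 with the block, which gave 10 genes with higher 3′ UTR use. With at least 5 counts per window 14573 sites were higher and 8007 lower, and with at least 20 counts 4208 and 1983. An estimated correlation left 0 lists (camera, 1 at an unadjusted p under 0.05), and also 0 with the block and 0 with CDS counts alone (0 unadjusted). With 2 libraries per group that setting can find little, so it does not show that correlation within the lists undid the calls.

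Leaving out each library in turn gave 127 to 1431 higher and 115 to 1116 lower genes, 2853 to 5554 higher and 13 to 45 lower 5′ UTRs, 72 to 309 and 47 to 950 CDS, and 4 to 122 and 18 to 232 3′ UTRs. 5′ UTR use was higher in 1898 to 5226 genes and lower in 1 to 16, CDS use in 0 to 54 and 21 to 708, and 3′ UTR use in 0 to 86 and 28 to 611. Sites numbered 0 to 10171 higher and 0 to 2591 lower, the 0 being without IP replicate 2 (edgeR, 39371 windows at an unadjusted p under 0.05). Lists past the threshold numbered 5 to 10. The 5′ UTR share stayed 17.2 to 22.8 points above the input, the CDS share 7.20 to 15.8 below and the 3′ UTR share 4.00 to 13.1 below. The lone library of a group was assumed to vary like the other group, and 2 libraries per group limit what can be found. Median log2 fold changes over all genes were -0.03 with TMM and 0.04 with library totals.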

Other observations

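The comparison of sites with other annotated transcripts was chosen after the results were seen.

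Of 1221 higher sites outside genes, 171 (14.0%) lay within 300 nt before an annotated 5′ end, beside 29 of 1354 (2.14%) lower sites. The mitochondrial chromosome took 1.71% and 1.79% of window counts in the IPs and 1.62% and 2.26% in the inputs.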
